A study of Mus musculus with 5 samples.

How the data were processed

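RNA was measured by sequencing of poly(A)-selected libraries from 5 sorted populations of mouse adipose stem cells. Per the labels, stromal cells of subcutaneous (SAT) and visceral (VAT) fat came from 30 wild-type mice aged 12 to 14 weeks. Cells positive for CD31 or CD45 were gated out, and the rest were sorted on CD26 and CD142. The authors deposited counts: 1 table of raw read counts per Ensembl gene, which had not been normalized. The deposited table also gives a gene length for each gene in another unit, bases. The processing notes of the labels list CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and mm10. The annotation release was not stated. Of the 54532 genes in the table, 54495 were found in GENCODE mouse release 21, and 53585 had an identical start and end there. In the table, 27 symbols are written as dates, and these genes were never named.

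Libraries were grouped by their titles. Titles and library names give the same gate for the 3 VAT libraries. For the 2 SAT libraries they give opposite gates, so each comparison that uses the SAT gates was made by title and again by library name. No library was reassigned from its values. The libraries are named here by depot and by the number that ends their library name. By title, 3 of the groups hold 1 library and 1 group, VAT CD26-CD142+, holds 2. The libraries share no other label that would pair them.

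Total counts ran from 21706345 to 25357403 per library. Counts were scaled by the trimmed mean of M values (TMM) in edgeR and are given as CPM. Intervals at 95% are exact Poisson for a count, exact Clopper-Pearson for a share and exact conditional for a ratio of 2 libraries or groups. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A ratio against libraries that are all at 0 was computed against a floor of 3 counts over the group and is written as a lower bound. Differences between depots in the gate effect are given as fitted, without such a bound.

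Genes were kept by filterByExpr at a minimum count of 10 with depot as the group, which left 15920 genes and removed 38612. Tests were edgeR quasi-likelihood F tests with robust dispersion, with Benjamini-Hochberg adjustment at 0.05 over all tested genes. The SE given with a log2 change is the size of the change divided by the square root of F. It is not a fitted standard error, and it can be too small for genes with few counts on a side, such as Wt1. Depot was tested over all gates with 3 residual degrees of freedom. The contrasts between gates used a 4-group fit with 1 residual degree of freedom, which comes from the pair of VAT CD26-CD142+ libraries, and each lone library was assumed to vary like that pair. The CD26 gate was tested with depot as a term, with 2 residual degrees of freedom. The difference between depots in the gate effect was tested in the 4-group fit. The labels do not say whether the libraries come from separate pools of mice. The spread in all these tests may therefore not be the spread between animals. The 2 SAT libraries, and the CD26+ libraries of the 2 depots, were compared without a test. There, genes at least 2-fold apart with a pseudocount of 1 CPM and at least 10 CPM in the higher library were counted.

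In all, 29 gene lists were fixed beforehand. They cover CD26+ interstitial, CD142+ (Areg), committed preadipocyte and pan-mesenchymal progenitor markers; mature adipocyte, thermogenic, subcutaneous developmental, visceral developmental and HOX genes. They also cover extracellular matrix, inflammatory, complement, interferon, retinoid, Wnt, TGF-beta and BMP, cell cycle, immediate early and mitochondrially encoded genes. Cell type lists are mesothelial, endothelial, macrophage, lymphocyte, mural, Schwann, mammary and skin epithelial, epididymal, skeletal muscle and erythrocyte markers. For depot over all gates, camera tested 28 lists at a preset correlation of 0.01; the epididymal list has 2 measured genes and was not tested. Camera with an estimated correlation and fry were run beside it. For other comparisons, the median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

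The named genes were chosen by rule: in each direction, the 12 largest changes among genes past the threshold, or at least 2-fold apart where there was no test. Each had every library of one side above every library of the other and at least 10 CPM in every library of the higher side. Only protein-coding genes with an established symbol counted. Where fewer than 12 passed, the next genes by unadjusted p were added and are said not to pass. For the difference between depots in the gate effect, separation of the sides cannot apply, and genes needed 10 CPM in 1 library; that rule was set after the data were seen. Any gene of a list may be named with its list.

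Groups, comparisons, lists, naming rule and the first set of alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a filter of 5 CPM in 2 libraries, DESeq2, limma-voom, each library left out, the library number as a block, CD26 status as a term, fits of fewer groups, and library names in place of titles. For comparisons without a test they were pseudocounts of 0.1 and 5 CPM, a minimum of 1 CPM, total-count scaling and DESeq2 size factors. Alternatives chosen after seeing the data were the libraries numbered 2 alone, mitochondrially encoded genes left out, the by-name groups with each setting, VAT CD26-CD142+ library 2 alone as reference, and removal of each library's trend with gene length. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

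The fits were tested on simulated data with 200 changed genes among 15920. Counts were drawn independently for each gene from the trended dispersion, without an effect of the library number. False calls in the real data may therefore be more frequent than given here. With edgeR, 48 of 100 genes changed 4-fold and 91 of 100 changed 8-fold were recovered between depots, with 5 unchanged genes among 144 calls. For the VAT gates these were 60 and 97, with 16 unchanged among 173, which is above the nominal share. For depot in the CD142+ gate they were 49 and 96, with 4 among 149. For the CD26 gate they were 14 and 70, with 1 among 85, and for the difference between depots 8 and 32, with 1 among 41. DESeq2 made 212 calls between depots, 46 of them unchanged genes. In the simulated list test, the 1 changed list passed and 0 of the unchanged lists did. In a simulated pair of libraries with counting noise alone, 0 of 9287 genes were 2-fold apart.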

Results

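Expression was measured in 5 libraries of fat progenitors from chow-fed mice, 2 from SAT and 3 from VAT, sorted on CD26 and CD142. CD26, encoded by Dpp4, marks interstitial progenitors that give rise to other fat progenitors. CD142 is tissue factor, encoded by F3, and marks progenitors known as Aregs, which were reported to restrain adipogenesis. By title there is 1 SAT CD26+CD142- library, 1 SAT CD26-CD142+ library, a pair of VAT CD26-CD142+ libraries and 1 VAT CD26+CD142+ library. SAT library 1 is titled CD26+CD142- but named for CD142, and SAT library 2 is titled CD26-CD142+ but named for CD26. Total counts were 25357403 in SAT library 1, 22259327 in SAT library 2, 21706345 and 23021617 in VAT CD26-CD142+ libraries 1 and 2, and 22477559 in the VAT CD26+CD142+ library. Mitochondrially encoded genes took 2.83% (95% interval 2.82 to 2.84) of counts in SAT library 1 and 4.33% (4.32 to 4.34) in VAT CD26-CD142+ library 1. In the 3 libraries numbered 2 they took between 0.554% and 0.633%.

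The sort genes followed the library names and not the titles in SAT. Dpp4 (ENSMUSG00000035000, mm10 chromosome 2, 62330073 to 62412231) was at 6.58 CPM (5.57 to 7.71) in SAT library 1, titled CD26+, and at 1007 CPM (994 to 1020) in SAT library 2, titled CD26-. F3 (ENSMUSG00000028128, chromosome 3, 121723537 to 121735048) was at 618 CPM (608 to 629) in SAT library 1, titled CD142-, and at 5.32 CPM (4.41 to 6.37) in SAT library 2, titled CD142+. In VAT, where titles and names give the same gates, Dpp4 was at 417 CPM (409 to 425) in the CD26+CD142+ library against 5.13 and 6.58 CPM in the CD26-CD142+ libraries. F3 was at 99.1 CPM (95.2 to 103) in the VAT CD26+CD142+ library against 379 and 241 CPM. Pecam1, the gene of the excluded CD31, was between 2.32 and 7.26 CPM in the 5 libraries. Ptprc, the gene of the excluded CD45, was between 0.183 and 0.989 CPM.

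**Figure D1:**
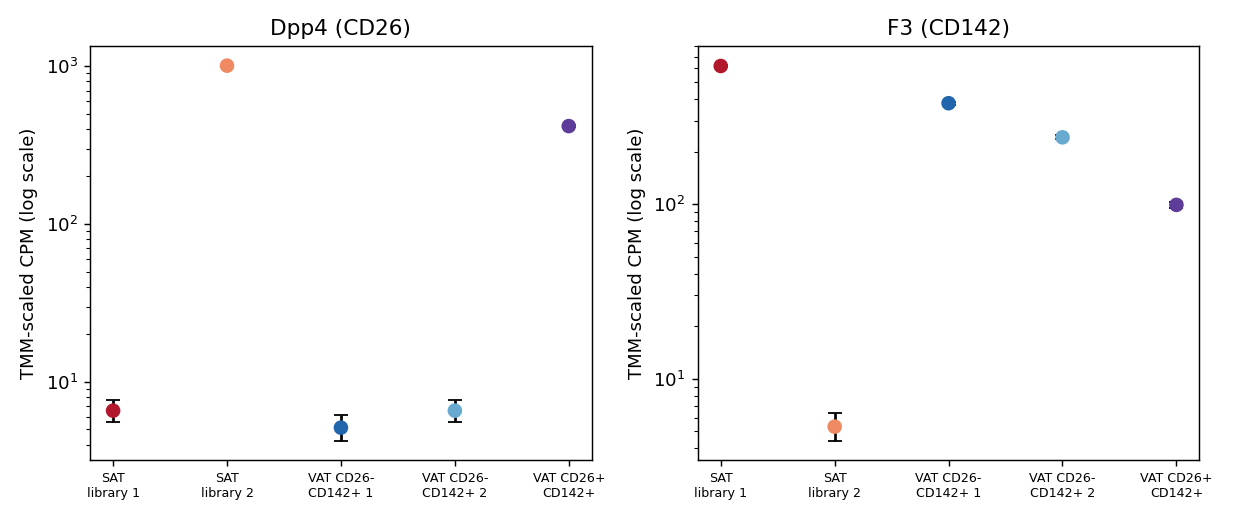
TMM-scaled CPM of Dpp4 (left) and F3 (right) in each of the 5 libraries on log axes, with bars for 95% Poisson intervals. Dpp4 is at 1007 CPM in SAT library 2 and 417 CPM in the VAT CD26+CD142+ library, and under 7 CPM in the other 3 libraries.

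Whether fat progenitors keep a depot identity was addressed by SAT against VAT over all gates, which does not depend on the SAT gate labels. Genes of developmental transcription factors were among those that passed. Tbx15 (ENSMUSG00000027868, chromosome 3, 99240381 to 99354259), a T-box factor of subcutaneous fat, was at 113 ± 22.5 CPM (SD, n = 2) in SAT and 0.203 ± 0.0731 CPM (SD, n = 3) in VAT, a log2 change of 9.09 (SE 0.39, adjusted p = 0.0172). Wt1 (ENSMUSG00000016458, chromosome 2, 105126529 to 105173616), a factor of visceral progenitors and mesothelium, was at 0.0226 ± 0.0319 CPM in SAT and 127 ± 24.0 CPM in VAT (log2 change -12.16, SE 0.67, adjusted p = 0.0224). From 1 count in SAT, this was 5735-fold lower in SAT (counting interval 1029 to 226544). Shox2, a homeobox gene, rose by 11.03 (SE 0.76, adjusted p = 0.0453), which is 2912-fold from 1 count in VAT (counting interval 522 to 115087).

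In all, 6 genes rose and 2 fell in SAT, and 15912 did not pass. The others that rose were Irx2 (log2 6.33, SE 0.35), the retinol-oxidizing dehydrogenase gene Adh7 (6.98, SE 0.48), the chemokine gene Ccl8 (4.79, SE 0.37) and Mab21l1 (5.50, SE 0.42), which is under 10 CPM in SAT library 1. Cadps, a gene of vesicle release, fell by 10.00 (SE 0.75, adjusted p = 0.0453). All 8 had the same direction between the libraries numbered 1 and between those numbered 2, which calls on all libraries largely fix. The next genes, Cyp4b1 (2.75, adjusted p = 0.125), Lgals3 (1.81, adjusted p = 0.146), Chrdl1 (3.80) and En1 (3.77) on the SAT side and Map7d2 (-4.38, adjusted p = 0.112), Slit2 (-3.44), Abat (-2.28) and Col6a5 (-6.97, adjusted p = 0.146) on the VAT side, did not pass. Dpp4 (1.83, SE 2.37) and F3 (0.38, SE 1.55) did not pass either. The 8 calls depend on each VAT library: with edgeR, 0 genes passed without VAT CD26-CD142+ library 1 (933 at unadjusted p under 0.05), without its library 2 (578) or without the VAT CD26+CD142+ library (1005). Without SAT library 1, 17 genes passed, and 11 without SAT library 2. They depend on the model too: 0 genes passed with limma-voom (978 at unadjusted p under 0.05), and with edgeR 0 passed with CD26 status by title as a term (682) or in the libraries numbered 2 alone (1439), while DESeq2 gave 465. With edgeR, 70 passed with no filter, 83 with CD26 status by name as a term, 5 with the number as a block and 4 with the length trend removed.

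**Figure D2:**
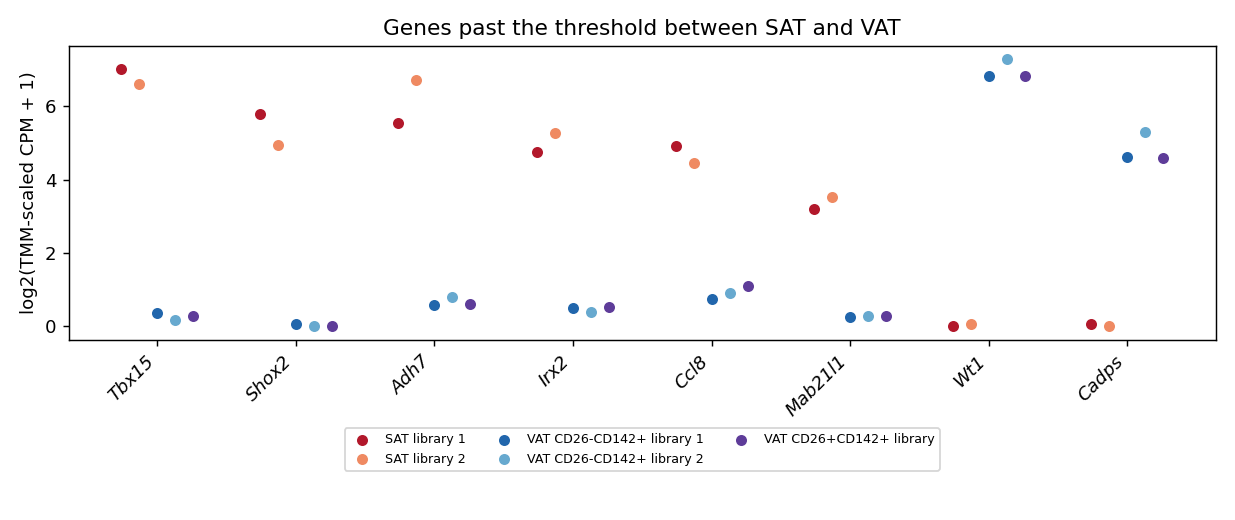
Log2 of TMM-scaled CPM plus 1 for the 8 genes past the threshold between SAT and VAT, with 1 point per library. Each gene separates the 2 SAT libraries from the 3 VAT libraries, as for Tbx15 with means of 113 and 0.203 CPM.

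The subcutaneous developmental list was higher in SAT as a whole. All 11 measured genes were higher, 2 (Tbx15, Shox2) passed over all genes and 11 passed adjusted over the list alone. The median log2 difference was 4.97, and camera gave adjusted p = 5.44e-53 and adjusted p = 0.0167 with an estimated correlation. Hoxc10 (4.97, SE 0.62), Irx1 (8.32, SE 0.91), En1 (3.77, SE 0.44) and the Wnt inhibitor Sfrp2 (3.32, SE 0.82) were among those that passed over the list alone. Of the 12 visceral developmental genes, Wt1 passed over all genes and 6 were lower adjusted over the list alone, among them Tcf21 (-8.39, SE 1.22), Hoxa5 (-2.91, SE 0.44) and Gata6 (-1.09, SE 0.22). Their median was -1.27 (camera adjusted p = 7.01e-14; adjusted p = 0.179 with an estimated correlation). HOX genes were mixed: adjusted over the list alone, 4 of 25 were higher (Hoxc9, Hoxa9, Hoxa10, Hoxc10) and 4 lower (Hoxa5, Hoxb5, Hoxa3, Hoxc4), and camera gave adjusted p = 0.911.

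Interferon response genes were higher in SAT in all 21 cases. None passed over all genes, and 5 passed adjusted over the list alone: the antiviral gene Oas2 (2.66, SE 0.34), Isg15 (2.32, SE 0.29), Usp18 (2.16, SE 0.57), Igtp (1.96, SE 0.42) and Bst2 (1.42, SE 0.28). The list's median was 0.97 (camera adjusted p = 4.24e-13; adjusted p = 0.247 with an estimated correlation). Of 26 inflammatory genes, Ccl8 passed over all genes and 5 were higher adjusted over the list alone, with Cxcl13 (5.28, SE 0.67), Cxcl5 (2.88, SE 0.41) and the alarmin Il33 (2.19, SE 0.51) (camera adjusted p = 8.68e-06; adjusted p = 0.247 with an estimated correlation). Among 37 matrix genes none passed over all genes and Mmp3 (6.54, SE 0.82) passed over the list alone. This list had camera adjusted p = 0.00177 (adjusted p = 0.404 with an estimated correlation; 0.107 without SAT library 1 and 0.0713 without VAT CD26-CD142+ library 1). Of 8 thermogenic genes Lhx8 (at least 147-fold higher) and Tmem26 (3.02, SE 0.66) passed over the list alone (camera adjusted p = 0.00237; adjusted p = 0.247 with an estimated correlation).

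Mesothelial markers were lower in SAT for 12 of 16 genes, with a median of -4.12, or -3.91 with the 2 genes at 0 in SAT set at their bound (camera adjusted p = 4.13e-07; adjusted p = 0.401 with an estimated correlation); Wt1, which is also a visceral developmental gene, was the 1 that passed. Of 13 pan-mesenchymal markers 4 were higher adjusted over the list alone, the stem cell antigen Ly6a (1.37, SE 0.37), Prrx1 (1.82, SE 0.39), Cd44 (0.94, SE 0.25) and Col1a1 (2.54, SE 0.52). Camera gave that list adjusted p = 0.0156 (adjusted p = 0.267 with an estimated correlation; 0.107 without SAT library 1, 0.0531 without VAT CD26-CD142+ library 1 and 0.0869 with the library number as a block). Of 13 complement genes 0 passed in either way, C4b being the largest (3.02, SE 0.64), with camera adjusted p = 0.0496 (adjusted p = 0.335 with an estimated correlation; 0.111 without SAT library 1, 0.0938 without VAT CD26-CD142+ library 1, 0.0951 without the VAT CD26+CD142+ library, 0.0869 with the block and 0.0503 with DESeq2 size factors). With fry by direction, 2 lists passed, the subcutaneous (adjusted p = 0.00518) and the visceral developmental list (adjusted p = 0.0423).

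The other tested lists did not pass in camera between depots with all libraries and no block. Adjusted p was 0.535 for CD26+ interstitial, 0.869 for Areg and 0.169 for committed preadipocyte markers, and 0.687 for mature adipocyte genes. It was 0.962 for retinoid genes, 0.874 for Wnt genes, 0.962 for TGF-beta and BMP genes, 0.609 for cell cycle genes, 0.107 for immediate early genes and 0.753 for mitochondrially encoded genes. For cell type markers it was 0.308 (endothelial), 0.920 (macrophage), 0.609 (lymphocyte), 0.920 (mural), 0.371 (Schwann), 0.874 (mammary and skin epithelial, over 3 genes past the filter and without Epcam and Csn3), 0.0787 (skeletal muscle) and 0.962 (erythrocyte). The runs below used the preset correlation of 0.01, and those without SAT library 1 or 2 set 1 SAT library of 1 gate against VAT. The filter was rerun with each library left out, so a list could gain or lose genes. Without SAT library 2, Epcam and Csn3, which were seen in SAT library 1, could enter the epithelial list. With all libraries, the estimated correlation was 0.941 for CD26+ interstitial, 0.881 for Areg, 0.905 for committed preadipocyte and 0.988 for mitochondrially encoded genes. For these lists the adjusted p below therefore overstates the evidence. With the library number as a block, committed preadipocyte markers (adjusted p = 0.0105) and immediate early genes (adjusted p = 0.0446) passed, both lower in SAT. Without SAT library 1, these 2 lists (8.14e-10 and 0.0465), Areg (6.06e-09), mature adipocyte (0.0352) and skeletal muscle genes (0.0457) passed as lower in SAT, and CD26+ interstitial (1.79e-06) and endothelial markers (0.00966) as higher. Without SAT library 2, CD26+ interstitial markers (9.02e-04) passed as lower, and Areg (3.13e-07), lymphocyte (0.0305), Schwann (0.00722), mammary and skin epithelial (2.71e-05) and mitochondrially encoded genes (0.0234) as higher. Mitochondrially encoded genes also passed as higher without VAT CD26-CD142+ library 1 (3.77e-05). Without the VAT CD26+CD142+ library, preadipocyte (0.00228) and immediate early genes (0.0193) passed as lower and CD26+ interstitial markers (1.35e-05) as higher. The median of the 2 epididymal genes was 0.12. The median had the opposite sign to the test for retinoid, Wnt, TGF-beta and BMP, macrophage and erythrocyte genes, and the mean did for HOX genes.

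Depot was also compared within the CD142+ gate, where the SAT side rests on the SAT gate labels. Tbx15 and Shox2 were higher in SAT whichever SAT library was used. Tbx15 was at 97.2 CPM in SAT library 2, the one titled CD26-CD142+, against 0.202 ± 0.103 CPM (SD, n = 2) in VAT (log2 change 8.88, SE 0.63). It was at 129 CPM in SAT library 1, the one named CD142 (9.29, SE 0.64). Shox2 was higher by 10.07 (SE 0.79) by title and by 10.92 (SE 0.79) by name. Tcf21, a factor of visceral progenitors, fell by 12.07 (SE 0.97) by title and by 7.43 (SE 0.72) by name, from 1 count in SAT library 2 and 29 counts in SAT library 1. Genes of the gates went with the choice: Dpp4 was higher in SAT by 7.42 (SE 0.56, adjusted p = 1.79e-06) by title and by 0.17 (SE 0.52, adjusted p = 0.994) by name.

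By title, 446 genes rose and 586 fell in the SAT library titled CD26-CD142+, where F3 was at 5.32 CPM. By name, 217 rose and 158 fell in the SAT library named CD142, where F3 was at 618 CPM. Of these genes, 247 passed both ways. With no filter, 727 passed by name. Of 1032 genes by title 818 had the same direction between libraries numbered 1 and between those numbered 2, and of 375 by name 307 did. The calls largely fix the pair that holds the SAT library used: all 1032 agreed in number 2 by title and all 375 in number 1 by name. The other pair takes the SAT library of the other gate, so it does not repeat the comparison within the CD142+ gate. Subcutaneous developmental genes rose in 10 of 11 cases by title and in 9 of 11 by name. Interferon genes rose in 8 of 21 cases by title and 2 by name, Isg15 (2.49, SE 0.48) and Oas2, with 6 adjusted over the list alone. By title, 16 of 20 CD26+ interstitial markers rose and 9 of 12 Areg markers fell, and by name 1 rose (Wnt2) and 1 fell of the former and 3 of the latter rose. By name, the protease gene Mmp3 (6.71, SE 0.56), Lhx8 (at least 163-fold higher), the keratins Krt18 (6.43, SE 0.63) and Krt8 (6.31, SE 0.65) rose, and Wt1 (at least 1036-fold lower), Cadps (-9.30, SE 0.97) and the retinaldehyde dehydrogenase gene Aldh1a3 (-5.94, SE 0.74) fell. The keratin change by name rests on SAT library 1, where the epithelial genes Epcam (25.2 CPM), Csn3 (17.0 CPM) and Krt19 (63.7 CPM) were also seen. By name, more genes fell than rose with DESeq2 and with the filter of 5 CPM, and by title more rose than fell with limma-voom. Mitochondrially encoded genes took 0.554% of counts in SAT library 2 and 2.83% in SAT library 1. They took 4.33% and 0.633% in VAT CD26-CD142+ libraries 1 and 2. The lone SAT library has no replicate.

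Within VAT, CD26+CD142+ cells were compared with CD26-CD142+ cells, whose labels do not conflict. CD26+ interstitial markers were among the genes that rose. Dpp4 was 70.9-fold higher (log2 change 6.15, SE 0.54, adjusted p = 6.72e-05), at 417 CPM against 5.86 ± 1.02 CPM (SD, n = 2). Pi16, a secreted marker of interstitial progenitors, was at 2083 CPM against a mean of 305 CPM (2.77, SE 0.54), and the Wnt inhibitor gene Dact2 was at 216 CPM against 3.85 ± 2.40 CPM (5.81, SE 0.58). The adipogenic receptor gene Pparg fell, from 28.8 ± 2.65 to 2.18 CPM (-3.72, SE 0.59), as did Car3 (-5.25, SE 0.64) and Apoe (-4.38, SE 0.72). F3 was lower by 1.65 on the log2 scale without passing (-1.65, SE 0.56, adjusted p = 0.246).

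In VAT, 143 genes rose and 111 fell in CD26+CD142+ cells. The total of 254 was 410 with upper-quartile scaling and 491 with no filter, and with DESeq2 more genes fell (190) than rose (167). Mitochondrially encoded genes were lower in CD26+CD142+ cells in all 12 cases without passing (median -2.37), and VAT CD26-CD142+ library 1 stood apart, as they took 4.33% of its counts against 0.633% in library 2 and 0.620% in the CD26+CD142+ library. With these genes left out, 297 genes passed. Genes that rose included Nov (5.68, SE 0.51), the bone morphogenetic protein gene Bmp7 (5.44, SE 0.52), the peroxide-forming oxidase gene Duox1 (5.84, SE 0.91) with its partner Duoxa1 (6.49, SE 0.68), Mrgprg (8.37, SE 0.76) and Bco1 (8.74, SE 1.05). Those that fell included Agt, the angiotensinogen gene (-4.74, SE 0.66), Cxcl14 (-4.93, SE 0.68), Trf (-4.78, SE 0.82), Gatm (-5.29, SE 0.82) and Fam83a (-6.29, SE 0.80). Of 20 CD26+ interstitial markers 14 rose over all genes and 19 adjusted over the list alone, Axin2 being the exception, with a list median of 2.76. Of 16 committed preadipocyte markers 4 fell (Car3, Apoe, Pparg, Sdc1) and 13 did adjusted over the list alone. Of 12 Areg markers 0 passed over all genes and 7 were lower adjusted over the list alone, among them Adamts15 (-2.31), Mgp (-1.98) and Gdf10 (-1.54).

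Of 16 mesothelial markers 5 rose, Msln (4.59, SE 0.66, at 38.5 CPM against 1.59 ± 1.15 CPM), Krt7 (5.02, SE 0.72), Krt8 (3.89, SE 0.63), Krt18 (2.94, SE 0.60) and Gpm6a (5.25, SE 0.95), and 9 rose adjusted over the list alone. Upk3b was at 96.2 CPM against 4.37 ± 5.73 CPM without passing (4.45, SE 1.74), and Cldn15 was lower over the list alone (-2.29, SE 0.55). Mature adipocyte genes had a median of -1.56 with 1 of 18 passing, and mural markers had a median of -1.56 with 2 of 11 passing, both lower. The lone CD26+CD142+ library has no replicate.

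**Figure D3:**
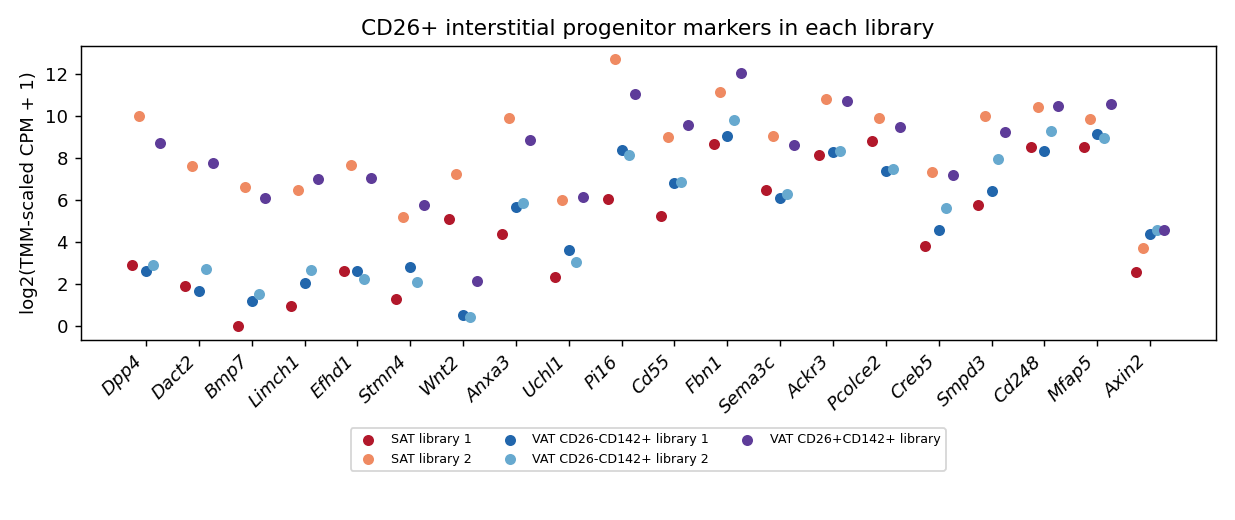
Log2 of TMM-scaled CPM plus 1 for the 20 CD26+ interstitial progenitor markers, with 1 point per library. Dpp4, at 1007 CPM in SAT library 2 and 417 CPM in the VAT CD26+CD142+ library, is under 7 CPM in the other 3 libraries.

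**Figure D4:**
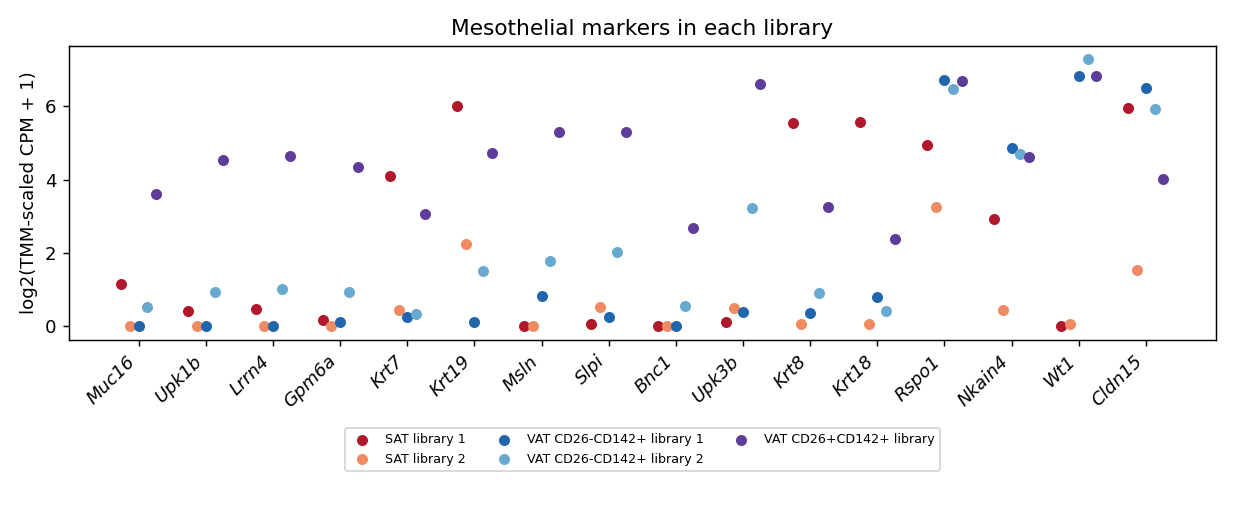
Log2 of TMM-scaled CPM plus 1 for the 16 measured mesothelial markers, with 1 point per library. Upk3b reaches 96.2 CPM in the VAT CD26+CD142+ library, and Krt8 reaches 45.8 CPM in SAT library 1.

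The 2 SAT libraries, the contrast of CD26+CD142- with CD26-CD142+ cells by title, were compared without a test, since each is alone in its group and their numbers differ. By title, the direction was opposite to that of the gates in VAT. Dpp4 was 153-fold lower and Pi16 was 103-fold lower in the library titled CD26+CD142-. Bmp7, at 0 counts there against 96.5 CPM, was at least 744-fold lower. F3 was 116-fold higher in the library titled CD142-, Mgp 186-fold, the chemokine gene Cxcl14 96.7-fold, Clec11a 62.4-fold and Apoe 49.8-fold. By library name, each of these directions is the reverse.

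Between the SAT libraries 1081 genes were 2-fold higher and 1079 lower in the library titled CD26+CD142- of 9677 considered, against 283 and 631 of 9448 between the VAT CD26-CD142+ libraries 1 and 2. All 20 CD26+ interstitial markers were at least 2-fold lower in the library titled CD26+CD142- (median -3.71, percentile 0 of random lists). Of 12 Areg markers 11 were higher (median 3.43, percentile 100), as were 15 of 16 preadipocyte markers (median 2.70). The keratins Krt8 and Krt18, at 45.8 and 46.7 CPM in SAT library 1, each had 1 count in SAT library 2. Mitochondrially encoded genes were higher in SAT library 1 (median 2.58), and between the VAT CD26-CD142+ libraries, 1 against 2, their median was 2.96.

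CD26+ cells of the 2 depots were compared without a test, as SAT CD26+CD142- against VAT CD26+CD142+. Depot genes differed under either choice of SAT library. Tbx15 was 626-fold higher in SAT by title and 472-fold by name, Mmp3 was 367-fold and 131-fold higher, and Wt1 was at 112 CPM in VAT. CD26 genes depended on the choice. By title, Dpp4 was at 6.58 CPM in SAT against 417 CPM in VAT, and by name it was 2.41-fold higher in SAT (counting interval 2.36 to 2.47). By name, Wnt2, a ligand gene of the interstitial list, was 42.7-fold higher in SAT (34.4 to 53.6).

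By title, 1096 genes were 2-fold higher and 1108 lower in the SAT library titled CD26+CD142-. By name, 385 were higher and 450 lower in the SAT library named for CD26. Of 20 CD26+ interstitial markers 18 were lower in SAT by title (median -3.64). By name, 4 were higher, 0 were lower and 16 were under 2-fold (median 0.13). Subcutaneous developmental genes were higher for 8 of 11 by title and 10 of 11 by name. Interferon genes were higher for 7 and lower for 2 of 21 by title, and higher for 8 and lower for 0 by name. Mesothelial markers were lower in SAT for 10 of 16 by title and 12 of 16 by name.

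The CD26 gate over both depots, with depot as a term, asked for genes that go with CD26 wherever the cells came from. By title, 0 genes passed with edgeR, with 140 at unadjusted p under 0.05; limma-voom gave 0 and DESeq2 gave 16. Dpp4 itself had a log2 difference of 4.20 (SE 4.05, adjusted p = 1), and the named genes did not pass, among them Gfra2 (3.37, SE 0.61), with the smallest unadjusted p of them, and Krt19 (4.44, SE 1.06), with the largest difference. Of 16 mesothelial markers 8 were higher adjusted over the list alone. Among these, Krt7, Krt8 and Krt19 were at 16.1, 45.8 and 63.7 CPM in SAT library 1, where the epithelial gene Epcam was at 25.2 CPM. Without VAT CD26-CD142+ library 1 or 2, 0 genes passed with edgeR (113 and 49 at unadjusted p under 0.05). Leaving out SAT library 1 or SAT library 2 gave 383 and 356 genes, but leaves the VAT contrast alone, and leaving out the VAT CD26+CD142+ library gave 522, but leaves 1 SAT library against the other, so these counts do not test CD26 over both depots.

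By library name, genes passed for the CD26 gate, but the gate goes with the library number in part: both CD26+ libraries are numbered 2, and 2 of the 3 CD26- libraries are numbered 1. Mitochondrially encoded genes took 0.554% of counts in SAT library 2 and 0.620% in the VAT CD26+CD142+ library. In the CD26- libraries they took 2.83% (SAT library 1), 4.33% and 0.633% (VAT CD26-CD142+ libraries 1 and 2). With the number as a block, 0 genes passed with edgeR (1592 at unadjusted p under 0.05). Dpp4 rose by 6.64 (SE 0.40, adjusted p = 0.0368), Efhd1 by 5.07 (SE 0.28), Dact2 by 5.94 (SE 0.47), the receptor gene Ackr3 by 2.52 (SE 0.26) and the ligand gene Wnt10b by 5.08 (SE 0.57). Car3 (-5.77, SE 0.46), Agt (-4.75, SE 0.33), the ectoenzyme gene Cd38 (-3.65, SE 0.34) and Dio3 (-3.29, SE 0.33) fell. In all, 51 genes rose and 44 fell. With DESeq2, 569 rose and 769 fell, with no filter 359 rose and 416 fell, and with the length trend removed 119 rose and 96 fell. Of 20 CD26+ interstitial markers 10 rose and 19 did adjusted over the list alone; of 16 preadipocyte markers 3 fell and 14 did adjusted over the list alone; of 12 Areg markers 0 passed and 4 were lower over the list alone. Without VAT CD26-CD142+ library 2, the gate by name and the library number coincide in full, so genes that pass then cannot be assigned to CD26. The count was 138 without VAT CD26-CD142+ library 1 and 2034 without its library 2. It was 383 without SAT library 1, 356 without SAT library 2 and 522 without the VAT CD26+CD142+ library, which as by title leave the contrast of 1 depot.

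The difference between depots in the gate effect was tested both ways. By title or by name, the CD26+ gate is CD142- in SAT and CD142+ in VAT, so the contrasts compared also differ in CD142. Since F3 encodes CD142, a difference in F3 cannot be assigned to depot. By title, Dpp4 (-13.41, SE 1.00, adjusted p = 2.89e-06) and F3 (8.50, SE 0.94, adjusted p = 4.73e-05) differed, and 619 genes were higher and 434 lower in the SAT contrast than in the VAT contrast. By title, 19 of 20 CD26+ interstitial markers were lower and 11 of 12 Areg markers higher. By title, the total of 1053 was 1621 with no filter. By name, 6 were higher and 34 lower. The total of 40 was 9 with limma-voom, 85 with DESeq2, 136 with upper-quartile scaling, 78 with the filter of 5 CPM and 181 with no filter. By name, Dpp4 did not pass (1.10, SE 0.79, adjusted p = 1.00), while F3 did (-5.21, SE 0.83, adjusted p = 0.0109). By name, Bmp6 (9.35, SE 1.62) and Itgb7 (7.84, SE 1.11) had a larger gate effect in SAT. In signed value it was lower in SAT for Krt8 (-13.71, SE 1.32), Krt18 (-12.80, SE 1.24) and Mgp (-5.56, SE 0.84). Mgp was lower with CD26 in both depots, and more so in SAT, at 3.70 against 688 CPM. In VAT it was at 183 CPM against 820 and 624 CPM. Bmp6 had 0 counts in SAT library 1, and Krt8 and Krt18 had 1 count each in SAT library 2. The sizes for Bmp6, Krt8 and Krt18 are therefore set largely by the fit near 0 counts. Krt8 and Krt18 were at 45.8 and 46.7 CPM in SAT library 1, where the epithelial genes Epcam (25.2 CPM), Csn3 (17.0 CPM) and Krt19 (63.7 CPM) were seen, and at 8.53 and 4.16 CPM in the VAT CD26+CD142+ library, where 5 of 16 mesothelial markers, these keratins among them, rose. The SAT contrast holds 1 library per gate, whose numbers differ, so within SAT alone the gate and the number cannot be told apart. For the sort genes, the VAT CD26-CD142+ pair, which has both numbers in 1 gate, argues against the number. Dpp4 was at 5.13 and 6.58 CPM in that pair, against 6.58 and 1007 CPM in SAT libraries 1 and 2. F3 was at 379 and 241 CPM in the pair, against 618 and 5.32 CPM in SAT. For other genes this was not tested. With upper-quartile scaling the median of all genes by title was 0.16, against 0.04 with TMM.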

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

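Of the tests below, those for length, GC content, mitochondrially encoded genes and the further mesothelial list were set before their results were seen; the others were chosen after, as were the by-name comparisons combined with other settings. The further mesothelial list was itself written after the expression data were seen, but before its own values were.

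The difference between depots in the gate effect was tested with 1 library per SAT gate, whose numbers differ, and 1 VAT CD26+CD142+ library. Its only spread comes from the pair of VAT CD26-CD142+ libraries, so in SAT it cannot by itself part the gate from the number or from chance between libraries. For Dpp4, the values of that VAT pair given below argue against the number. By title, which values below argue against, 1053 genes passed, with Dpp4 at -13.41 and F3 at 8.50 on the log2 scale. By library name, 40 passed, with F3 at -5.21. By name, the SAT contrast was larger for Bmp6 (9.35), Bmp7 (8.68), Itgb7 (7.84), Aldh1a3 (6.73), Kcnn3 (6.49) and Sbsn (4.24). By name it was lower in signed value for Krt8 (-13.71), Krt18 (-12.80), Dsp (-10.63), Krt7 (-10.48), Aqp5 (-10.32), Prlr (-9.49), Ano1 (-8.19), Lrrn2 (-7.18), Aldh1a2 (-7.05), Gfra2 (-6.34), Kcnk2 (-6.25) and Mgp (-5.56). Of these, Krt8, Krt18, Krt7, Aqp5 and Prlr were at 45.8, 46.7, 16.1, 12.7 and 26.8 CPM in SAT library 1, the library with the epithelial genes Epcam (25.2 CPM), Csn3 (17.0 CPM) and Krt19 (63.7 CPM), and under 1 CPM in SAT library 2. Krt8, Krt18, Krt7 and Dsp also rose in the VAT CD26+CD142+ library, the first 3 as mesothelial markers. For these genes a difference in the gate effect and transcripts of other cell types were not separated. Several sizes are set largely by the fit near 0 counts, as Bmp6 and Bmp7 had 0 counts in SAT library 1. Krt8, Krt18, Aqp5, Prlr, Lrrn2 and Kcnk2 were at 0.0451 CPM (1 count) in SAT library 2. By label, the VAT CD26+ library was sorted CD142+ as well, so by name the gates compared also differ in CD142, with F3 at 99.1 CPM there against 5.32 CPM in SAT library 2.

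Title and library name give opposite gates for both SAT libraries. An effect of the library number is argued against, since Dpp4 differed by 0.31 (log2) between VAT CD26-CD142+ libraries 2 and 1 against 7.06 between SAT libraries 2 and 1. Correct titles with Dpp4 and F3 transcripts that part from the surface proteins are argued against too, as 0 of 19 other CD26+ interstitial markers were higher in the SAT library titled CD26+. An exchange of the 2 SAT titles is the candidate explanation that stays open: of 784 genes 2-fold apart between the VAT CD26+CD142+ library and VAT CD26-CD142+ library 2, with Dpp4 and F3 left out, 669 (85.3%) went the same way from SAT library 1 to 2. A biological difference between depots in what CD26 marks would, as the source of this conflict, need the SAT titles to be right, and the same values argue against that, with Dpp4 at 6.58 CPM in the SAT library titled CD26+ against 1007 CPM in the other.

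The VAT CD26-CD142+ libraries 1 and 2 differed at least 2-fold in 914 genes. GC content is argued against as the cause, with Spearman's rho of -0.00993 across 9194 genes, which are not independent replicates; it was 0.142 between SAT libraries 1 and 2 and -0.181 between the VAT CD26+CD142+ library and VAT CD26-CD142+ library 2. With mitochondrially encoded genes left out, 903 genes (98.8% as many) were 2-fold apart. That cannot decide whether counts taken by those genes play a part, since TMM scaling already allows for counts taken by a few genes. A gene length bias may explain part of the difference: rho with gene length was -0.600, and -0.494 between SAT libraries 1 and 2, against 0.0142 between the VAT CD26+CD142+ library and VAT CD26-CD142+ library 2, which share a number. With each library's trend with length removed, 502 genes stayed 2-fold apart, so length alone does not account for the rest, and a difference between the pools of cells stays open as untested.

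Of 16 mesothelial markers 5 passed as higher in the VAT CD26+CD142+ library. An effect of the library number is argued against, since 12 of all 16 measured markers (75.0%, 95% interval 47.6 to 92.7) were at least 2-fold higher than in VAT CD26-CD142+ library 2, which has the same number, against 3.61% of all tested genes. The exceptions were Rspo1, Nkain4, Wt1 and Cldn15. The interval treats the markers as independent, but their estimated correlation between depots was 0.455, so it is too narrow. VAT CD26-CD142+ library 2 is also 1 of the pair against which the markers were flagged, so this check is not independent of that result. RNA from mesothelial cells in the sorted pool may be part of the rise in these markers, as 4 of 6 genes (66.7%) of a further mesothelial list were at least 2-fold higher than in each VAT CD26-CD142+ library. That evidence is weak, since 3 of the 6 genes were at 10 CPM or more in SAT library 2 and 2 of the 4 were under 10 CPM there; of the 4, Ildr2 was at 170 CPM against 183 CPM in SAT library 2 and Pkhd1l1 at 43.8 CPM against 0 there, and the sort removed CD31 and CD45 cells but not mesothelial cells. Expression by CD26+CD142+ progenitors of VAT stays open as untested, since 1 bulk library holds both.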

How the results depend on the processing

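Chosen after the data were seen were the libraries numbered 2 alone, mitochondrially encoded genes left out, by-name groups with each setting, VAT CD26-CD142+ library 2 as sole reference, and removal of the length trend. A value under a test is called reversed here only if it passed under 1 of the settings. Over results and alternatives, 2068 values kept their direction and side of the threshold or their size, 128 lost the threshold, 84 gained it, 374 moved, most of them without a test, and 9 reversed. Unless a reason is given, the cause was not tested.

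Scaling by DESeq2 size factors left each count of genes within 1.5 times, and upper-quartile scaling did except for the VAT gates (410 genes) and the gate-by-depot difference by name (136). With no filter, which tests more genes, counts were 70 between depots, 727 for depot in the CD142+ gate by name, 491 for the VAT gates, 775 for the CD26 gate by name, and 1621 by title and 181 by name for the difference. The filter of 5 CPM gave 78 for the difference by name. DESeq2 gave 465 between depots, 16 by title and 1338 by name for the CD26 gate and 85 for the difference by name; limma-voom gave 0 between depots (978 at unadjusted p under 0.05) and 9 for the difference by name.

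Leaving out 1 library gave 0 to 17 genes between depots, 0 to 522 for the CD26 gate by title and 138 to 2034 by name; without a SAT library or the VAT CD26+CD142+ library, the CD26 gate is contrasted in 1 depot only. Without VAT CD26-CD142+ library 2, the CD26 gate by name coincides with the library number. Without 1 of the VAT CD26-CD142+ libraries the fits of the CD142+ gate and the VAT gates have no residual degrees of freedom, and no test was run. Between depots the number as a block gave 5 genes, CD26 status by title 0 (682 at unadjusted p under 0.05), CD26 status by name 83, and the libraries numbered 2 alone 0 (1439). With the block the CD26 gate by name gave 0 (1592). Whether the numbers pair the libraries cannot be decided from fewer than 3 pairs, and the SAT libraries differ in gate as well. Across 15920 genes, which are not independent, r of the differences of SAT libraries 1 and 2 and of VAT CD26-CD142+ libraries 1 and 2 was 0.483. The share of mitochondrially encoded genes and the trend with gene length also went with the number in both depots.

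By library name, counts were 375 for depot in the CD142+ gate, 95 for the CD26 gate, 40 for the difference and 835 for CD26+ cells. By name, Mrgprg (-3.20), Dmkn (-0.35) and Dhrs9 (-1.25) reversed for depot in the CD142+ gate, and Clec11a (-0.50), Sema3e (0.48) and Bmp7 (0.50) for CD26+ cells; the use of the other SAT library is the cause by construction. For comparisons without a test, a minimum of 1 CPM, which counts more genes, gave 3321 between SAT libraries, 3310 for CD26+ cells by title and 1438 by name. Against VAT CD26-CD142+ library 2 alone 786 genes were 2-fold apart in VAT. Removal of the length trend gave 4 genes between depots and 215 for the CD26 gate by name.

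Of gene lists, 9 passed between depots, 1 with an estimated correlation, 2 with fry by direction and 15 with fry in either direction. Leaving out 1 library gave 7 to 15, the latter without SAT library 2. Areg markers reversed without SAT library 1 (adjusted p = 6.06e-09; 6.06e-09 to 0.840 over the libraries left out). CD26+ interstitial markers (adjusted p = 9.02e-04; 1.79e-06 to 0.964) and mammary and skin epithelial markers (adjusted p = 2.71e-05; 2.71e-05 to 0.921) reversed without SAT library 2; each leaves 1 SAT gate against VAT. The filter was also rerun with each library left out, and without SAT library 2 it kept 17204 genes against 15920. Those runs therefore need not hold the same list genes as the main run, and the epithelial list could gain genes seen in SAT library 1 alone. The subcutaneous developmental list passed in every alternative run.

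Depth limits genes near the floor of 3 counts, where ratios such as those of Shox2, Wt1 and Cadps have wide intervals.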

Other observations

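The liver plasma protein genes were chosen only after their levels in these libraries had been noticed.

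Of 16 liver plasma protein genes, 15 were higher in both libraries numbered 1 than in each of the other 3, without a test. Alb was at 106 CPM in SAT library 1 and 52.7 CPM in VAT CD26-CD142+ library 1, and at 3.97, 3.74 and 3.92 CPM in SAT library 2, VAT CD26-CD142+ library 2 and the VAT CD26+CD142+ library. Apoa1 was at 39.6 and 16.9 CPM in the libraries numbered 1 and at 1.22, 1.85 and 1.36 CPM in the other 3. Mup20, a major urinary protein gene, was at 21.5 and 5.23 CPM against 0.0451, 0.473 and 0.577 CPM. The exception was Hp, which fat also expresses. It followed the depot and was at 42.9 and 11.5 CPM in the SAT libraries and between 561 and 658 CPM in the VAT libraries, so the sum over all 16 was 413 CPM in SAT library 1 and 735, 670 and 571 CPM in VAT CD26-CD142+ libraries 1 and 2 and the VAT CD26+CD142+ library. Without Hp it was 370 and 168 CPM in the libraries numbered 1 and between 8.57 and 11.9 CPM in the others.

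Epithelial genes were seen in SAT library 1. Epcam was at 25.2 CPM there and at most at 0.0860 CPM in the other 4 libraries, the milk protein gene Csn3 was at 17.0 CPM there and at 0 in the others, and Krt19 was at 63.7 CPM there, at 25.6 CPM in the VAT CD26+CD142+ library and at most at 3.74 CPM in the other 3. The epithelial list as fixed beforehand was not highest in SAT library 1, at 28.3 CPM against 298 and 98.4 CPM in VAT CD26-CD142+ libraries 1 and 2, but its sum covers 3 genes past the filter, without Epcam and Csn3, and Trf makes up most of it in those VAT libraries (288 and 93.1 CPM). Krt5 had 2 counts and Krt14 had 0 counts in SAT library 1.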
